A study of Mus musculus with 12 samples.

How the data were processed

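RNA was extracted from sorted cells and made into libraries with a stranded poly(A) mRNA kit, per the labels' protocols. The deposited table of raw counts holds whole-number counts per gene for 12 libraries, per the file headers, and the deposited FPKM table holds the same libraries scaled by gene length and size factor, per the file headers. STAR, Picard and DESeq2 1.30.0 and the builds mm10 and GRCm38 are named in the submitters' processing notes, with no role given. The counter, its strand setting and its treatment of reads shared between genes are not given in the sources used here. On 11921 genes with at least 20 counts, the FPKM values equalled the counts divided by one length per gene and one size factor per library, so the tables are one measurement in different units. Columns were matched to groups by their names, which show cell type and genotype but no replicate number, and libraries are therefore numbered as in the columns.

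The table held 55487 genes, of which 28299 had a count in at least 1 library, and no row lacked a gene name. Of the gene identifiers, 55141 were in GENCODE M21 (GRCm38), and 99.42% of those had the same location there; coordinates are those of the deposited table. Total counts ranged from 11606251 to 24320247, the 10 most abundant genes took 3.59% to 4.66% of counts, and mitochondrially encoded genes 1.02% to 1.60%. Libraries of a group differed by more than sampling noise (chi-square of 2.33 to 6.33 per gene) and correlated across genes at Pearson r of 0.990 to 0.995, so each was kept as 1 replicate.

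Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr by group kept 15905 genes, TMM factors ranged from 0.968 to 1.04, and 1 quasi-likelihood model with a coefficient per group was fitted to all 12 libraries with robust estimation. The biological coefficient of variation was 5.21%. Contrasts were KO against WT in naive and in effector cells, the difference between these, and effector against naive in WT and in KO. P-values were adjusted over all tested genes by the Benjamini-Hochberg method at 0.05, and standard errors were taken from the fold change and the F statistic. CPM are TMM-normalised. For a gene at 0 in a group the fold is a bound against 3 counts over the group, or 0.060 CPM in WT naive; such bounds cover counting error only.

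The 25 gene lists held 422 symbols, 3 of which were not matched: Tfh, Th1, Th2, Th17 and Treg programmes, naive state, effector and memory, early T cell receptor response, CD28 and NF-kB, PI3K with AKT and FOXO, RAB5 and endosome, cell cycle, interferon response, glycolysis, cholesterol synthesis, cell handling stress, mitochondrially encoded mRNAs, and markers of B cells, plasma cells, CD8 T cells, NK with NKT and gamma-delta T cells, myeloid cells, erythroid cells with platelets, stromal cells, and Y-linked genes with Xist. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of each comparison, and again with an estimated correlation and with fry. With an estimated correlation no list kept its call in naive or effector cells for KO against WT, the Th1, Th17, naive state and effector and memory lists kept it for effector against naive in WT, and the Th1, effector and memory, and NK lists kept it for the difference of the KO effects. With fry, 10 lists passed in naive and 10 in effector cells for KO against WT, where camera gave 14 and 16. Among them were the interferon list (fry adjusted p = 0.0019 and 6.7e-04), the Treg list (0.018 and 0.028) and the Th1 list (0.013 as higher and 0.024 as lower). Genes within 5 Mb of Rinl and genes changed in both cell types were tested with two-sided Fisher's exact tests, Rinl left out.

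Named genes followed a rule: Rinl; the 10 largest rises and 10 largest falls among called genes with non-overlapping libraries and at least 5 CPM in the higher group, leaving out gene models without a name and antigen receptor segments; up to 4 called members of each list by p; and always Cd44, Bcl6, Cxcr5, Pdcd1, Icos, Il21, Tbx21, Gata3 and Foxp3. Some genes that the rule names are not reported here. The groups, contrasts, main model, lists, this rule and the alternatives were chosen before the data were examined, except those said in the closing section to be chosen later. The alternatives were DESeq2's size factors in edgeR, DESeq2 1.42.0, limma-voom, no filter on low counts, a mean of at least 5 CPM, a fit of only the groups compared, limma on log2 of FPKM plus 1 or plus 0.1, each library left out, windows of 1 and 20 Mb, and an overlap threshold of 0.1.

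The model was tested on simulated counts drawn from the means and library sizes of these libraries. Each gene had 1 spread, the same in all groups, as the model assumes. The test therefore cannot show how the model does where the spread differs between groups. Seeded genes had a mean of at least 5 CPM in both cell types. In naive cells 92.0% of 100 genes seeded at a log2 change of 0.5 and 99.0% of 100 seeded at 1 were recovered, and in effector cells 84.0% and 100%. False calls were 6.4% of calls in the naive, 10.9% in the effector and 4.1% in the simulated difference. The adjusted p threshold was 0.05. False calls thus lay above it in effector cells (24 of 221 calls), slightly above it in naive cells (13 of 204) and below it for the difference (15 of 369). Figures were drawn with matplotlib 3.10.9.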

Results

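The data are messenger RNA profiles of CD4+ T cells sorted by flow cytometry from mouse spleen and peripheral lymph nodes. Naive cells, which have not met antigen, were sorted as CD44 low and effector cells as CD44 high, among other surface markers. Both populations came from wild-type (WT) mice and from mice lacking Rinl (KO), to ask what Rinl does in CD4+ T cells. Rinl encodes a Ras and Rab interactor-like protein, a guanine nucleotide exchange factor of RAB5 family small GTPases, which direct early endosome traffic. Each of the 4 groups held 3 libraries, numbered 1 to 3 for WT naive, 4 to 6 for WT effector, 7 to 9 for KO naive and 10 to 12 for KO effector. Total counts per library ran from 12409965 to 19584111 in WT naive, from 12893396 to 16428862 in WT effector, from 20072199 to 24320247 in KO naive and from 11606251 to 20381010 in KO effector. Levels below are CPM, counts scaled to a common library size, given as mean ± SD over 3 libraries, and fold changes are log2 values ± SE. Nothing in the labels says that the 3 libraries of a group came from separate animals, so the p-values measure only the spread between these libraries. The first principal component held 86.6% of the variance and separated naive from effector libraries, and the second held 2.86%, with all 6 WT libraries above 0 and all 6 KO libraries below.

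Rinl was lower in all KO libraries. In WT naive libraries 1, 2 and 3 it stood at 298, 299 and 286 CPM, and in KO naive libraries 7, 8 and 9 at 32.6, 32.2 and 34.4 CPM. In WT effector libraries 4, 5 and 6 it stood at 437, 451 and 463 CPM, and in KO effector libraries 10, 11 and 12 at 45.8, 47.5 and 49.4 CPM. The log2 fold change of Rinl (ENSMUSG00000051735, GRCm38 chromosome 7, 28788969 to 28798963, plus strand) was -3.16 ± 0.049 in naive cells (edgeR adjusted p = 4.3e-23) and -3.24 ± 0.049 in effector cells (edgeR adjusted p = 2.0e-23). The difference between these changes was -0.09 (edgeR adjusted p = 0.74). Which part of Rinl was altered is not given in the sources used here, so the remaining counts cannot be placed inside or outside it.

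**Figure D1:**
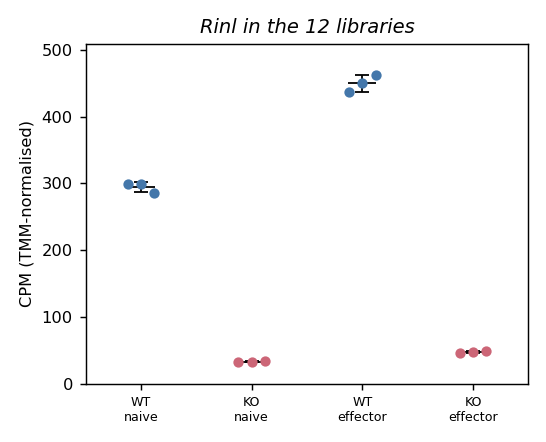
Rinl in CPM (TMM-normalised) in each of the 12 libraries by group; points are libraries, and the black dash and bars are the group mean and SD. The 6 KO libraries sit between 32.2 and 49.4 CPM and the 6 WT libraries between 286 and 463 CPM.

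The comparison of WT effector with WT naive cells describes the sorted populations. Cd44, which encodes a surface protein used in the sort, went from 18.8 ± 1.42 to 257 ± 2.33 CPM. Genes of helper subsets were higher in effector cells: Tbx21, the T-bet transcription factor of T helper 1 (Th1) cells, rose from 0.331 ± 0.091 to 93.4 ± 13.9 CPM, and Foxp3 of regulatory T cells (Treg) from 48.6 ± 2.81 to 353 ± 36.5 CPM. Cxcr5 and Pdcd1, receptors of T follicular helper (Tfh) cells, rose by log2 values of 4.70 ± 0.18 and 4.84 ± 0.22, and Icos, a costimulatory receptor, by 2.61 ± 0.09. Genes of the naive state fell, among them Igfbp4 (log2 fold change -6.04), the lymph node homing receptor Ccr7 (-2.39), and the transcription factors Lef1 (-2.26) and Satb1 (-1.76). Dntt, the polymerase of antigen receptor gene assembly (-6.98), Ampd1 (-5.16) and Dapl1 (-4.48) also fell.

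All 17 tested genes of the Th1 list rose in WT effector cells, including the chemokine Ccl5 (9.35) and the granule gene Nkg7 (7.87), as did all 8 of the T helper 17 (Th17) list, including Ccr6 (6.51) and Ahr (3.96), and all 20 of the effector and memory list, including Itgb1 (4.05), S100a6 (8.97) and the interleukin-2 receptor chain Il2rb (3.76). The camera adjusted p-values were 3.6e-11, 6.9e-07 and 7.8e-14, and 0.0098, 0.018 and 0.0083 with an estimated correlation. Of the naive list 19 of 20 genes fell and 1 rose (camera adjusted p = 7.5e-13, adjusted p = 0.018 with an estimated correlation). The Treg list had 18 of 19 genes higher, among them Ctla4 (4.02) and Entpd1 (4.81), and the Tfh list 18 of 20 higher and 1 lower, among them P2rx7 (3.59) and Batf (1.54), with camera adjusted p = 5.5e-13 and 5.3e-09. Both calls were lost at adjusted p = 0.052 and 0.12 with an estimated correlation. Of 6 markers of NK, NKT and gamma-delta T cells, 5 were higher and 1 lower: Klrk1 went from 0.125 ± 0.135 to 67.9 ± 5.31 CPM, and Zbtb16, at 0 in all 3 WT naive libraries and 42.8 ± 7.07 CPM in WT effector, was at least 709-fold higher against a floor of 3 counts over the group. That list had camera adjusted p = 0.0043, and adjusted p = 0.12 with an estimated correlation. In Th2 cell genes, 8 of 10 rose, including Gata3 (1.28), and 2 fell, including Il4ra (-1.26), with camera adjusted p = 0.0029 and adjusted p = 0.11 with an estimated correlation. Of 26 cell cycle genes, 19 were higher, such as Mki67 (4.89) and Top2a (1.91), and 3 lower, with camera adjusted p = 1.4e-04 and adjusted p = 0.12 with an estimated correlation. Counts adjusted over the list alone were the same for these lists, except 20 higher for the cell cycle.

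Other lists moved in WT effector cells as well. Early T cell receptor response genes were higher in 16 of 20, such as the transcription factor Irf4 (3.61) and Spry1 (3.33), and 1 was lower (18 and 1 adjusted over the list alone; camera adjusted p = 6.3e-07, adjusted p = 0.11 with an estimated correlation). Of 21 CD28 and NF-kB genes, 15 rose, such as Icam1 (2.02), and 4 fell, such as the adaptor gene Grap2 (-1.06), with camera adjusted p = 0.021 and adjusted p = 0.15 with an estimated correlation. Of 21 PI3K, AKT and FOXO genes, 11 fell, such as Pik3ip1 (-1.62) and Foxo1 (-0.92), and 5 rose (camera adjusted p = 0.030, adjusted p = 0.15 with an estimated correlation). Of 17 glycolysis genes, 14 rose, among them the hexokinase gene Hk2 (3.36), and 1 fell, with camera adjusted p = 0.0015 and adjusted p = 0.15 with an estimated correlation. Of 21 cholesterol synthesis genes, 12 fell, such as Hmgcs1 (-0.60), and 2 rose, and all 9 mitochondrially encoded mRNAs fell, with camera adjusted p = 0.013 and 0.0027, and adjusted p = 0.36 and 0.32 with an estimated correlation. Interferon genes went both ways, 16 higher, such as Mx1 (2.56), and 5 lower, such as Oas2 (-1.80), with camera adjusted p = 0.046 and adjusted p = 0.46 with an estimated correlation. Of B cell markers 9 of 15 rose, among them Cd22 (5.82), and of plasma cell markers 4 of 6, with camera adjusted p = 0.010 and 0.029, and adjusted p = 0.25 and 0.12 with an estimated correlation. The RAB5 and endosome list did not pass with camera (camera adjusted p = 0.22) but did with fry (fry adjusted p = 9.4e-08). In it Rin2, a relative of Rinl, went from 0.071 ± 0.082 to 15.5 ± 1.11 CPM, Eea1 rose (4.44) and Als2cl fell from 1242 ± 62.7 to 288 ± 14.0 CPM. Rinl itself was higher in WT effector than in WT naive cells (0.61). The lists of cell handling (camera adjusted p = 0.52), CD8 T cells (0.36), myeloid cells (0.22), erythroid cells and platelets (0.85), stromal cells (0.92) and Y-linked genes with Xist (0.72) did not pass with camera either. Of these, the CD8 T cell list passed with fry (fry adjusted p = 9.4e-08). With fry 20 of the 25 lists passed in this comparison, so a pass by it sets a list little apart. Adjusted over the list alone, 15 CD28 and NF-kB genes rose and 5 fell, 6 and 12 of the PI3K list, 3 and 13 of cholesterol synthesis and 11 and 0 of B cell markers, and the glycolysis, interferon, mitochondrial and plasma cell counts were the same. In all, 8933 of 15905 genes differed, 4808 higher and 4125 lower in effector cells. In KO cells the same comparison gave 9281 genes, 5023 higher and 4258 lower, with Cd44 at 3.60, Tbx21 at 6.94, Foxp3 at 2.95 and Cxcr5 at 4.61. No alternative moved either count by over 1.5 times.

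In naive cells, the number of genes changed with loss of Rinl depended on the fit, and most changes were small. Several of the largest were in genes close to Rinl, and of the gene lists the interferon-induced genes had the most members higher. Fbxo17, an F-box protein gene of the family that recognises glycoproteins, rose from 12.7 ± 0.742 to 94.4 ± 3.02 CPM (log2 2.89 ± 0.066, edgeR adjusted p = 1.5e-19). Its neighbour and relative Fbxo27 rose from 1.90 ± 0.295 to 19.5 ± 1.49 CPM (3.39 ± 0.15, edgeR adjusted p = 1.8e-13); how reads shared by related genes were counted is not given in the sources used here. The zinc finger gene Zfp974 fell from 12.5 ± 2.18 to 4.76 ± 0.484 CPM (-1.41 ± 0.14) and the galectin gene Lgals4 from 15.5 ± 1.09 to 7.42 ± 0.398 CPM (-1.07 ± 0.12). Among named genes away from Rinl with at least 5 CPM in the higher group, the largest falls were in Bmf, a pro-apoptotic BH3-only gene (-1.02), Tmem267 (-0.96), the endocytic adaptor Ston1 (-0.96), the arrestin-domain gene Arrdc3 (-0.92), the activin receptor Acvr2a (-0.70), Nacc2 (-0.62) and the G protein gene Gnal (-0.61). Rises of such genes included Ighg2c, an immunoglobulin G constant region (0.115 ± 0.134 to 5.36 ± 2.77 CPM), the immediate early gene Fos (0.80), the interferon-induced Mx1 (0.75) and Isg15 (0.55), Lad1 (0.58), Drc1 (0.55) and the transcriptional repressor Gfi1 (0.52). Blvrb, on chromosome 7 within 5 Mb of Rinl, rose as well (0.58). In all, 187 of 15905 genes changed, 108 higher and 79 lower, of which 33 changed at least 2-fold and 132 by less than 1.4-fold.

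Of 25 interferon response genes, 12 rose in KO naive cells, 0 fell and 13 did not pass, with a median log2 fold change of 0.31 (22 rose adjusted over the list alone). Ifit1 rose from 58.4 ± 5.11 to 80.3 ± 7.37 CPM, Oasl2 from 27.8 ± 1.02 to 38.9 ± 1.69 CPM, and Zbp1, a nucleic acid sensor, from 169.9 ± 4.23 to 204 ± 10.2 CPM. The camera adjusted p of this list was 1.9e-21, and adjusted p = 0.055 with an estimated correlation. In the CD28 and NF-kB list 4 of 21 genes rose, namely Nfkb2 (0.32), Icam1 (0.30), Relb (0.30) and Tnfaip3 (0.24), with 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0013, adjusted p = 0.12 with an estimated correlation). In the early T cell receptor response list, Cd69 rose (0.25) and 19 genes did not pass, against 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0098, adjusted p = 0.36 with an estimated correlation). Of 20 naive state genes, 4 fell, over all genes and adjusted over the list alone: S1pr1, the receptor for lymphoid organ exit (-0.22), Foxp1 (-0.22), Atp1b1 (-0.31) and the interleukin-7 receptor Il7r (-0.52). That list had camera adjusted p = 2.0e-04, and adjusted p = 0.16 with an estimated correlation.

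Several genes of effector cells were raised at low levels in the KO naive libraries. Ccl5 rose from 0.415 ± 0.178 to 1.52 ± 0.402 CPM and S100a6 from 0.269 ± 0.094 to 1.02 ± 0.093 CPM, against 268 ± 23.1 and 135 ± 13.1 CPM in WT effector cells. Il12rb1 (0.43) also rose. So did Il2rb (0.30), which was not at a low level, with 87.7 CPM in WT and 107 CPM in KO naive libraries. The Th1 list had 2 of 17 genes higher (3 adjusted over the list alone; camera adjusted p = 2.4e-04, adjusted p = 0.12 with an estimated correlation) and the effector and memory list 2 of 20 (2 adjusted over the list alone; camera adjusted p = 0.0069, adjusted p = 0.16 with an estimated correlation). The Treg list had 0 of 19 genes past the threshold over all genes and 7 higher adjusted over the list alone (camera adjusted p = 1.4e-09, adjusted p = 0.12 with an estimated correlation), and Foxp3 stood at 48.6 ± 2.81 and 58.3 ± 2.60 CPM (0.27, edgeR adjusted p = 0.15; it passed under 4 of 20 alternatives). The Th17 list had 0 of 8 genes past it by either adjustment (camera adjusted p = 0.028, adjusted p = 0.18 with an estimated correlation). Markers of other cells moved the same way: medians were 0.87 for the B cell list, 1.18 for the myeloid list and 2.10 for the NK, NKT and gamma-delta T cell list, with 0 genes called over all genes and 5, 4 and 2 higher adjusted over the list alone. Their camera adjusted p-values were 2.5e-05, 2.0e-04 and 2.0e-04, and adjusted p = 0.12, 0.34 and 0.12 with an estimated correlation. The light chain gene Igkc, for example, was 5.81 ± 5.70 CPM in WT and 30.7 ± 4.78 CPM in KO naive libraries (2.60, edgeR adjusted p = 0.058).

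Of 16 genes of the cell handling list, 3 rose in naive cells, namely the heat shock genes Dnajb1 (0.32) and Dnaja1 (0.29) and Fos, with 5 adjusted over the list alone (camera adjusted p = 2.0e-04, adjusted p = 0.18 with an estimated correlation). Cholesterol synthesis genes had a median of -0.15 with 0 of 21 called and 3 lower adjusted over the list alone (camera adjusted p = 9.6e-07, adjusted p = 0.15 with an estimated correlation). Mitochondrially encoded mRNAs had a median of -0.26 with 0 of 9 called and 1 lower adjusted over the list alone (camera adjusted p = 7.2e-04, adjusted p = 0.34 with an estimated correlation). In lists that did not pass, Pik3ip1, an inhibitor of PI3 kinase, fell (-0.23) in the PI3K, AKT and FOXO list (camera adjusted p = 0.38), and Appl2, an effector of RAB5 on endosomes, fell (-0.29) in the RAB5 and endosome list (camera adjusted p = 0.44). The camera adjusted p was 0.37 for the Tfh list, 0.99 for Th2, 0.40 for the cell cycle, 0.098 for glycolysis, 0.37 for plasma cells, 0.77 for CD8 T cells, 0.37 for erythroid cells and platelets, 0.77 for stromal cells and 0.68 for Y-linked genes with Xist. The sort gene Cd44 (0.01) did not pass, nor did Bcl6 (-0.13), Cxcr5 (0.55; it passed under 1 of 20 alternatives), Pdcd1 (0.16), Icos (-0.18), Tbx21 (0.53) or Gata3 (-0.02), and Il21 was near 0 in both groups (0.063 and 0.060 CPM). All 187 called genes had 3 libraries of one genotype above the 3 of the other, as did 20.5% of all genes tested, where chance gives 10%. Leaving out library 2, 7, 8 or 9 gave 72, 124, 66 and 84 genes, a fit of the naive libraries alone gave 580, and 30 of the 40 named genes called in naive cells lost their call under at least 1 alternative, Ighg2c, Il12rb1 and Isg15 among them.

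In effector cells, loss of Rinl went with mostly small changes. Most interferon-induced genes and some Treg genes rose, and some Th1 and effector genes fell, but none of these lists kept its call with an estimated correlation. Among named genes with at least 5 CPM in the higher group, the largest falls were in Rinl and the skin-homing chemokine receptor Ccr10, from 9.53 ± 1.55 to 2.49 ± 0.864 CPM (-1.88 ± 0.21, edgeR adjusted p = 1.6e-05). Next came Lgals4 (-1.54), Cntnap1 (-1.34), the ADP receptor P2ry1 (-1.11), Zfp974 (-1.06), the carnitine transporter family gene Slc22a4 (-1.01), Tmem267 (-0.995), Pdlim4 (-0.97) and Bmf (-0.92). Ccr10 lies within the span of Cntnap1, and how reads of overlapping genes were counted is not given in the sources used here. Rises included Ighg2c (0.757 ± 0.488 to 7.58 ± 3.75 CPM), Fbxo17 (1.89 ± 0.077), Col16a1 (1.37), Padi4, a citrullinating enzyme (1.14), the interferon-induced Ifi44 (1.02), Tmc3 (0.98), the sugar transporter Slc2a6 (0.96), Fam83g (0.93) and the decoy interleukin-1 receptor Il1r2 (0.92). In all, 503 of 15905 genes changed, 230 higher and 273 lower, of which 44 changed at least 2-fold and 337 by less than 1.4-fold.

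Of 25 interferon response genes, 18 rose in KO effector cells, 0 fell and 7 did not pass, with a median of 0.32 (23 rose adjusted over the list alone). Oasl2 rose from 24.2 ± 1.68 to 37.9 ± 3.76 CPM, Oas1a from 44.3 ± 1.21 to 60.9 ± 2.28 CPM and Ifit1 from 56.8 ± 2.07 to 81.5 ± 3.41 CPM. The camera adjusted p was 2.8e-21, and adjusted p = 0.057 with an estimated correlation. The B cell and myeloid lists also had medians above 0 in KO effector libraries, 0.46 and 0.80, with 1 and 0 genes called, 5 higher and 1 lower of the B cell list adjusted over the list alone, and 0 of the myeloid list. Their camera adjusted p-values were 0.0041 and 0.0019, and adjusted p = 0.24 and 0.48 with an estimated correlation. The 1 called B cell gene was Cd22, which fell (-0.60).

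Of 17 Th1 genes, 6 fell, 0 rose and 11 did not pass (9 fell adjusted over the list alone). Tbx21 fell from 93.4 ± 13.9 to 61.8 ± 3.35 CPM (-0.59), Nkg7 from 147.8 ± 13.9 to 99.2 ± 9.23 CPM (-0.57), the granule protease gene Ctsw from 131.6 ± 8.87 to 95.3 ± 5.75 CPM (-0.46) and Ccl5 from 268 ± 23.1 to 206 ± 13.7 CPM (-0.38). The camera adjusted p was 0.0014, and adjusted p = 0.23 with an estimated correlation. Of 20 effector and memory genes, 6 fell and 14 did not pass (13 fell and 2 rose adjusted over the list alone): the integrin Itgb1 went from 867 ± 37.5 to 681 ± 34.8 CPM, and Vim (-0.33), the transcriptional regulator Id2 (-0.50) and the chemokine receptor Ccr2 (-0.53) also fell. That list had camera adjusted p = 1.3e-04, and adjusted p = 0.15 with an estimated correlation. Markers of NK, NKT and gamma-delta T cells moved with them: Klrb1c (-0.47), Zbtb16, the transcription factor of NKT cells (-0.75), and Klrk1 (-0.53) fell, 3 of 6 genes (4 adjusted over the list alone; camera adjusted p = 0.010, adjusted p = 0.24 with an estimated correlation). Naive state genes fell too, 5 of 20 (6 adjusted over the list alone), among them S1pr1 (-0.24), Satb1 (-0.24), Il7r (-0.42) and the gut-homing receptor Ccr9 (-0.63), with camera adjusted p = 6.4e-04 and adjusted p = 0.24 with an estimated correlation.

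Of 19 Treg genes, 6 rose, 0 fell and 13 did not pass (9 rose adjusted over the list alone). Foxp3 rose from 353 ± 36.5 to 449 ± 38.2 CPM (0.35), Ctla4 from 198.7 ± 12.1 to 249 ± 12.3 CPM (0.33), the costimulatory receptor Tnfrsf4 from 161 ± 7.56 to 221 ± 27.6 CPM (0.46) and Gpr83 by 0.41. The camera adjusted p was 1.9e-06, and adjusted p = 0.24 with an estimated correlation. Of 20 Tfh genes, the transcription factors Tox (0.32) and Batf (0.30) rose and 18 did not pass, while 11 rose adjusted over the list alone (camera adjusted p = 1.9e-06, adjusted p = 0.24 with an estimated correlation). The Tfh genes named in advance did not pass: Cxcr5 was 111 ± 15.9 and 152 ± 24.7 CPM (0.46, edgeR adjusted p = 0.068), Pdcd1 136 ± 17.2 and 185 ± 41.4 CPM (0.45, edgeR adjusted p = 0.17) and Bcl6 51.0 ± 5.35 and 64.5 ± 12.1 CPM (0.34, edgeR adjusted p = 0.17). Il21 was 8.26 ± 3.92 and 12.9 ± 4.40 CPM (0.66, edgeR adjusted p = 0.30) and Icos 293 ± 20.9 and 303 ± 34.5 CPM (0.05, edgeR adjusted p = 0.82). Cd44 (-0.16, edgeR adjusted p = 0.084) and Gata3 (-0.02) did not pass either. Of 20 alternatives, Cxcr5 passed under 5, Bcl6 under 3, Cd44 under 2 and Il21 under 1, and Pdcd1, Icos and Gata3 under 0. Of 10 Th2 genes, the epithelial growth factor family gene Areg rose (1.13), the interleukin-25 receptor Il17rb fell (-0.71) and 8 did not pass (camera adjusted p = 0.67).

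**Figure D2:**
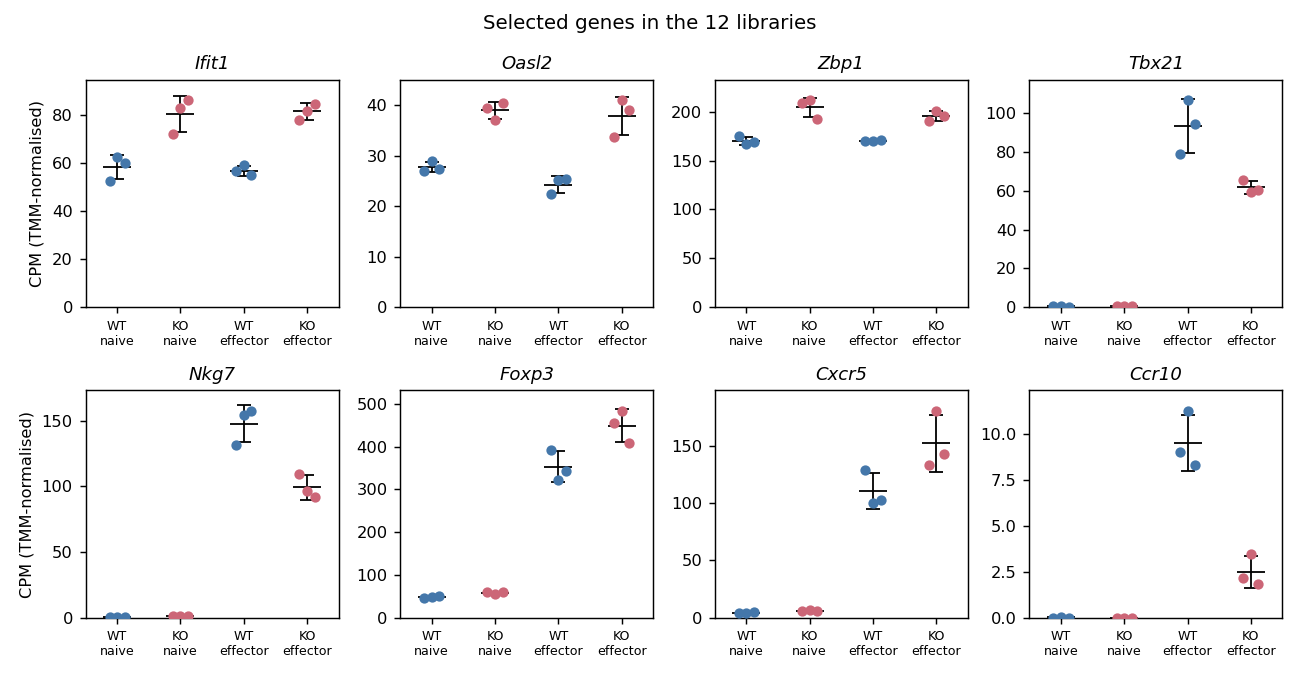
CPM (TMM-normalised) of 8 genes in each of the 12 libraries by group; points are libraries, and the black dash and bars are the group mean and SD. Ifit1 and Oasl2 are higher in the KO libraries of both cell types, Tbx21 goes from 93.4 to 61.8 CPM and Foxp3 from 353 to 449 CPM in effector cells, and Cxcr5 did not pass the test.

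In the early T cell receptor response list, Tnfrsf9 (0.39), Nfatc1 (0.23) and Nab2 (0.30) rose and Cd40lg, the ligand that T cells show to B cells, fell (-0.28), with 6 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.043, adjusted p = 0.52 with an estimated correlation). In the CD28 and NF-kB list Nfkb2 (0.25) and Relb (0.27) rose, with 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.034, adjusted p = 0.24 with an estimated correlation). Pik3ip1 (-0.35) and the kinase gene Sgk1 (-0.31) fell in the PI3K, AKT and FOXO list, with 5 lower adjusted over the list alone (camera adjusted p = 0.041, adjusted p = 0.24 with an estimated correlation). Of 26 RAB5 and endosome genes, Appl2 fell from 48.7 ± 2.64 to 33.3 ± 1.47 CPM (-0.55) and the early endosome tether Eea1 rose (0.38), with the same 2 counts adjusted over the list alone (camera adjusted p = 0.46). With fry that list passed as lower (fry adjusted p = 0.028), though its median was only -0.01. In the cell cycle list Hmgb2 fell (-0.31), with 3 lower adjusted over the list alone (camera adjusted p = 0.0019, adjusted p = 0.24 with an estimated correlation). Of the cell handling list Dnaja1 (0.32), Dnajb1 (0.28), Hspa8 (0.21) and Fos (0.63) rose, 4 of 16 genes by either adjustment (camera adjusted p = 0.0014, adjusted p = 0.24 with an estimated correlation). Cholesterol synthesis genes had a median of -0.08 and mitochondrially encoded mRNAs of 0.13, with 0 genes called by either adjustment; both had camera adjusted p = 0.034 and adjusted p = 0.52 with an estimated correlation. In the plasma cell list Txndc5 fell (-0.21; camera adjusted p = 0.45). The camera adjusted p was 0.45 for Th17 and for glycolysis, 0.98 for CD8 T cells and for erythroid cells and platelets, 0.67 for stromal cells and 0.45 for Y-linked genes with Xist. Of the 503 called genes, 493 had 3 libraries of one genotype above the 3 of the other, as did 17.9% of all genes tested, where chance gives 10%. Leaving out library 5, 6 or 11 gave 270, 267 and 194 genes, a fit of the effector libraries alone gave 241, and 39 of the 62 named genes called in effector cells lost their call under at least 1 alternative, Ighg2c, Sgk1, Eea1, Areg and Ccr9 among them.

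**Figure D3:**
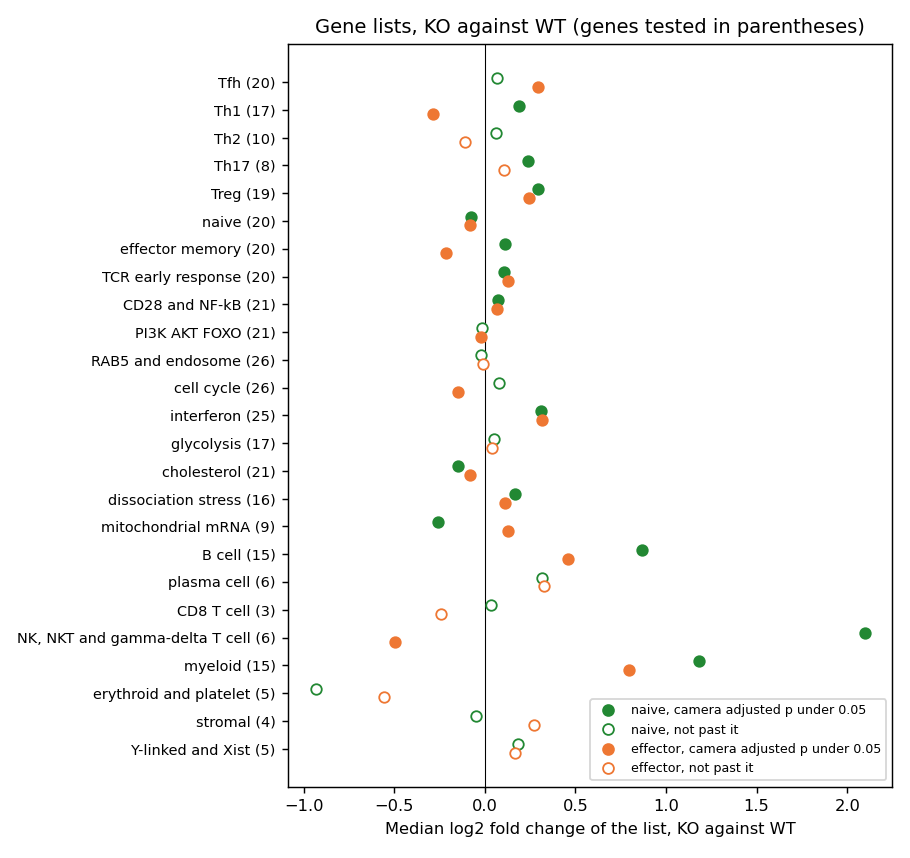
Median log2 fold change of each of the 25 gene lists, KO against WT, in naive (green) and effector (orange) cells; filled points have a camera adjusted p under 0.05 with the preset correlation and open points do not. The interferon list has medians of 0.31 and 0.32, while the Th1 list has medians of 0.19 and -0.29.

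The genotype effects in naive and effector cells, which share no library, overlapped. Whether the naive and effector libraries came from the same mice is not given in the sources used here. Besides Rinl, 70 genes changed in both, of which 37 rose in both and 30 fell in both, where independent lists give 1.56 and 1.33 (odds ratio 19.8, Fisher's exact test p = 4.5e-53). These references hold only if the cell types came from separate mice, since differences between mice shared by both would recur in both lists. Interferon-induced genes were among those higher in both, such as Usp18 (0.46 in naive and 0.67 in effector), Isg15 (0.55 and 0.52), Gbp5 (0.33 and 0.25) and Irgm1 (0.36 and 0.20). Cish, a feedback inhibitor of cytokine signalling, rose in both (0.43 and 0.32), and Dusp6, a phosphatase of ERK, fell in both (-0.35 and -0.44). Trat1, an adaptor of the T cell receptor (-0.27 and -0.53), and Arrdc3 (-0.92 and -0.61) fell in both. Of the 67 genes with the same direction, 56 lay outside 5 Mb of Rinl. Usp18, Gbp5, Irgm1, Cish, Dusp6 and Trat1 were chosen after their values were seen. Leaving out library 2, 8 or 9 gave 41, 31 and 34 genes with the same direction.

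Genes close to Rinl on chromosome 7 changed more often than others. In naive cells 19 of 195 genes tested within 5 Mb changed, or 9.74%, against 1.06% of the others (odds ratio 10.04, 95% interval 5.76 to 16.6, Fisher's exact test p = 1.4e-12). In effector cells 17 of 195 changed, or 8.72%, against 3.09% (odds ratio 3.00, interval 1.69 to 4.99, Fisher's exact test p = 1.5e-04). Fbxo17 lay 0.051 Mb from Rinl, Fbxo27 0.090 Mb, Lgals4 0.035 Mb and Zfp974 0.860 Mb. Within 1 Mb, 11 of 55 genes changed in each cell type. With a 20 Mb window the excess in effector cells no longer passed (odds ratio 1.52, Fisher's exact test p = 0.080).

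**Figure D4:**
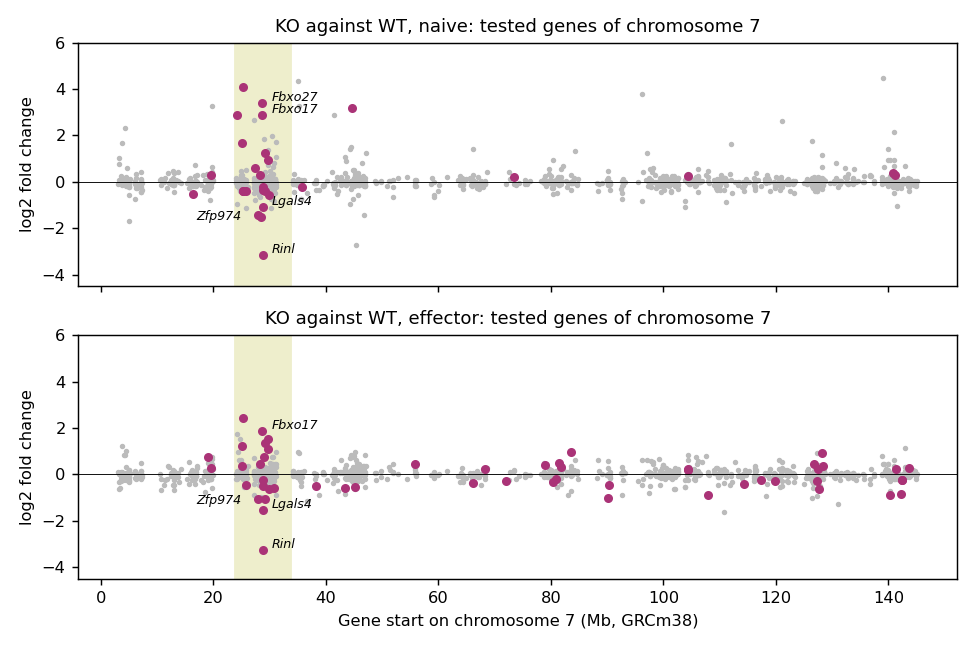
Log2 fold change, KO against WT, of every tested gene of chromosome 7 by gene start (Mb, GRCm38) in naive (top) and effector (bottom) cells; purple points have an edgeR adjusted p under 0.05 and the shaded band is 5 Mb on each side of Rinl. The band holds 19 called genes in naive and 17 in effector cells besides Rinl.

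The KO effect differed between effector and naive cells for 23 genes, 3 with a higher and 20 with a lower change in effector cells. Fbxo27 rose in naive cells but stood at 11.8 ± 2.03 and 14.4 ± 0.987 CPM in effector cells (difference -3.11 ± 0.20, edgeR adjusted p = 1.2e-09). Fbxo17 rose in both by different amounts (difference -0.99). Ccl5 (-2.25) and S100a6 (-2.15) belonged to the raised traces in naive cells described above, and Ctsw (-0.63), Jaml (-0.82) and Pdlim4 (-0.99) were lower in KO effector cells. The Th1 and effector and memory lists differed between the cell types (camera adjusted p = 3.8e-07 and 2.2e-07, adjusted p = 0.037 for both with an estimated correlation), each with 2 genes lower over all genes and with 6 and 7 adjusted over the list alone. So did the NK, NKT and gamma-delta T cell markers, with a larger median of -1.95, 0 genes lower over all genes and 2 adjusted over the list alone (camera adjusted p = 2.2e-06, adjusted p = 0.044 with an estimated correlation). These differences joined rises in naive with falls in effector cells. Medians were 0.19 and -0.29 for Th1, 0.11 and -0.215 for effector and memory, and 2.10 and -0.50 for NK markers. Part of the naive rises lay near 0, such as Klrk1 at 0.125 CPM in WT and 0.525 CPM in KO naive libraries, and their source stays open. The Tfh, cell cycle and mitochondrially encoded lists passed as well (camera adjusted p = 0.0011, 0.0011 and 2.5e-05) but not with an estimated correlation (adjusted p = 0.89, 0.41 and 0.49). The interferon list did not pass this test (camera adjusted p = 0.43). Leaving out library 2, 6, 7, 8 or 9 gave 11, 14, 12, 10 and 15 genes, and leaving out library 4, 10 or 12 gave 85, 47 and 39. DESeq2 gave 61 genes, no filter 277, and limma on FPKM plus 1 or plus 0.1 gave 13 and 8.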

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

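The tests of explanations below, and what counts over other splits of the libraries were taken to show, were chosen after the results had been seen; the tests of the difference between cell types were planned. What drew attention to the results here was a difference of the KO effect between effector and naive cells, by the test of that difference. It held for 23 genes (11, 14, 12, 10 and 15 without library 2, 6, 7, 8 or 9, and 85, 47 and 39 without library 4, 10 or 12). Among the named ones the log2 difference was 0.39 for St8sia1, a ganglioside synthase, -3.11 for Fbxo27, -2.25 for Ccl5, -2.15 for S100a6, -2.06 for Plac8, -1.59 for Myo1f, -0.996 for Lad1, -0.99 for Fbxo17, -0.99 for Pdlim4, -0.82 for Jaml, -0.63 for Ctsw and -0.44 for Il2rb. Among lists the camera adjusted p of the difference was 0.0011 for Tfh (adjusted p = 0.89 with an estimated correlation), 3.8e-07 for Th1 and 2.2e-07 for effector and memory (both adjusted p = 0.037 with an estimated correlation). It was 0.0011 for the cell cycle (adjusted p = 0.41 with an estimated correlation), 2.5e-05 for mitochondrially encoded mRNAs (adjusted p = 0.49) and 2.2e-06 for NK, NKT and gamma-delta T cell markers (adjusted p = 0.044).

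Of 100 splits drawn within the cell types, 3, the real one included, gave at least its 23 genes. These splits mix WT and KO libraries, so genotype effects shared by both cell types widen the spread within their groups. Their reference is no genotype effect at all, so they cannot exclude chance for a difference between the cell types. The highest other split, with 605 genes, points to a structure of the samples: it exchanges all 6 effector labels and keeps the naive ones, which turns the difference of the KO effects into their sum. The remaining one exchanges 4 naive labels and gave 55 genes. For the other counts the 6 libraries allow only 10 splits, too few for a share under 0.05. The real split gave 187 genes in naive cells and the highest other 1; in effector cells these were 503 and 20. For effector against naive they were 8933 and 0 in WT and 9281 and 0 in KO cells, and in each comparison 1 split, the real one, gave as many.

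Genes near Rinl changed more often in naive cells. Loss of Rinl acting alike on genes anywhere would give no excess there, which the odds ratio of 10.04 within 5 Mb argues against as the whole cause. An effect of the altered allele on neighbours within 1 Mb would give no excess further away. Genes 1 to 5 Mb away, 8 of 140, still changed more often than the rest in naive cells (odds ratio 5.64, Fisher's exact test p = 1.6e-04). That test takes neighbouring genes as independent, so it does not exclude such an effect as the whole cause. In effector cells that outer zone had 6 of 140 (odds ratio 1.41, Fisher's exact test p = 0.45). Variants of another strain linked to the altered allele stay open as a candidate explanation, so Fbxo17, Fbxo27, Zfp974 and Lgals4 may differ for reasons other than lost Rinl. Of the 19 genes called near Rinl in naive cells, 100% had the same sign in effector cells. Any genotype effect present in both cell types would give this, and genome-wide 67 of the 70 genes called in both shared their direction. The sign therefore does not tell these explanations apart.

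Effector-type transcripts stood higher in KO naive libraries: of 33 genes with at least 30 CPM in effector and at most 1% of that in naive cells, all 33 had a higher mean in KO naive, 14 with every KO library above every WT library. Of all genes tested in naive cells, 20.5% had no overlap, counting both directions together, where chance gives 10%. The median level was 0.534% to 0.679% of the effector level in libraries 7 to 9 and 0.250% to 0.391% in libraries 1 to 3 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). Greater depth of the KO naive libraries is argued against, since after thinning every library to the smallest total the lowest KO library still lay 0.244 percentage points above the highest WT one. More cells with the make-up of the effector gate would add one share to every gene, and this stays open. Shares ran from 0.038% for Ccr4 to 1.06% for Fgl2, and 0.0125 of 2000 simulated data sets with one share spread as widely. Over the 24 genes with an expected count of at least 20 it was 0.0015, so the wide spread was not confined to the lowest counts. That reference assumed the mean KO effector profile, was chosen after a chi-square of 2.04 per degree of freedom had been seen, and still rests on low levels. Open as well are a few cells of another make-up, such as those rich in Klrk1 and Nkg7, and myeloid or B lineage cells, whose 33 markers differed by 6.58 times as much in summed CPM (Igkc by 24.9 and Lyz2 by 6.67 CPM) but all 36 by only 1.05 times as much (Ighm, Xbp1 and Txndc5, with means above 50 CPM, were left out of the 33 after the first values were seen), though the sort for CD4 should remove them.

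Interferon-induced genes were higher in KO libraries of both cell types. Myeloid or B lineage cells would bring their own abundant transcripts. In naive libraries the summed rise of the interferon list was 5.39 times that of 33 markers of these cells, which argues against them there. With all 36 markers it was 33.7 times, but mostly because Ighm differed by -45.2 CPM. That cut the summed marker rise from 56.7 to 9.1 CPM, so the larger ratio adds no weight. In effector libraries the interferon rise was 4.43 times that of the 33 markers, but 1.60 times with all 36 (Ighm was 964 in WT and 1143 CPM in KO libraries, edgeR adjusted p = 0.074), so such cells stay open there. Cell handling stress stays open: the median of the interferon list lay above that of the stress list by 0.147 in naive and 0.206 in effector cells, but the means differed by no more than their spread once the correlation within each list was allowed for (0.163 ± 0.176 and 0.188 ± 0.191 SE; p = 0.18 and 0.16, one-sided normal test), and the interferon list was weighed because it had risen. Loss of Rinl and another difference between the KO and WT mice, such as housing or infection, cannot be told apart, because every KO library came from KO mice and no label gives a batch. Both could raise the list alike in both cell types, and neither has to. The test of the difference did not pass (camera adjusted p = 0.43) and does not tell them apart. An effect of Rinl on this response may thus be stated only as a hypothesis.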

How the results depend on the processing

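Leaving out libraries for list tests, for genes near Rinl and for the overlap, leaving out gene sets, and the block below were added after the data were seen; all other settings were planned. The columns carry no replicate numbers, so their order within a group stood in for the planned replicate block. Naive and effector libraries at the same place correlated at 0.025 to 0.163 in their deviations from the group means, over 0.1 in 2 of 6 pairs. Each of the 12 libraries correlated best with its own place, a hint from the data that only 5 kept over the 9963 genes above 5 CPM in every library (-0.173 to 0.252). Xist and Ddx3y ranked alike by place in both genotypes. A pairing by order is thus neither shown nor excluded, and the main test of the difference took none. As a replicate block the order gave 231, 515 and 43 genes for naive, effector and the difference, and within each genotype 87 for the difference; of lists 14, 16 and 6 passed, and 8 for the difference within each genotype. Named genes were not refitted with it. The sign of no called named gene was reversed under any other setting. For KO against WT in naive cells (187 genes), no filter gave 501, only the groups compared 580, FPKM plus 1 40, FPKM plus 0.1 57, and leaving out 1 library 66 to 255 (72 without library 2, 124 without 7, 66 without 8, 84 without 9). In effector cells (503) the same settings gave 959, 241, 262, 139 and 194 to 662 (270 without library 5, 267 without 6, 194 without 11). A fit of only the groups compared thus gave more genes in naive than in effector cells, the reverse of the main model. For the difference (23), DESeq2 gave 61, no filter 277, FPKM plus 1 13, FPKM plus 0.1 8, and leaving out 1 library 10 to 85 (11, 14, 12, 10 and 15 without library 2, 6, 7, 8 or 9, 85, 47 and 39 without 4, 10 or 12). Fewer libraries or other gene numbers change power and adjustment. Lower power would not by itself raise a count, as the fit of the naive groups alone did. Otherwise the cause was not tested. DESeq2's size factors gave 187, 507 and 23 genes, DESeq2 252 and 540, and voom 187, 541 and 17. Of the naive calls 169 were shared with voom. Effector calls were 230 higher and 273 lower, against 515 and 444 without a filter, 293 and 291 without library 10, and 260 and 220 without library 12. Under every other setting more were lower than higher. The difference had 3 higher and 20 lower calls, against 14 and 47 with DESeq2 and 84 and 193 without a filter. Without genes within 5 Mb of Rinl 160, 481 and 21 genes were called, and without genes over 20-fold higher in WT effector than WT naive cells 176, 394 and 19. Effector against naive stayed within 1.5 times in WT and KO. Of lists, 14 passed in naive and 0 with an estimated correlation; 16 in effector, 0 with it, 10 with fry and 10 to 16 without 1 library (10 without library 6); 6 for the difference, 3 with it and 3 with fry; 18 for effector against naive in WT and 4 with it. Near Rinl, the odds ratio was 22.4 at 1 Mb and 4.79 at 20 Mb in naive and 7.82 and 1.52 in effector cells, where the last no longer passed. Leaving out 1 library moved the odds ratio within 5 Mb to between 8.94 and 21.5 in naive and between 2.39 and 6.15 in effector cells. It passed each time. The overlap of 67 was 110 at a threshold of 0.1 and 31 to 71 without 1 library (41, 31 and 34 without library 2, 8 or 9). Of called named genes, 10 of 40 in naive cells kept their call under every setting run on them (Fbxo17, Fbxo27, Zfp974, Lgals4, Tmem267, Arrdc3, Gfi1, Ifit1, Oasl2 and Zbp1), as did 23 of 62 in effector cells, among them Ccr10, Itgb1, Tnfrsf4, Appl2 and Oasl2, and 3 of 12 for the difference. Of named genes not called, 2 of 11, 4 of 9 and 1 of 12 passed under some setting. Simulated recovery of 84.0% to 92.0% at a log2 change of 0.5 shows that smaller changes can be missed at this depth. Simulated false calls were 10.9% of effector calls, above the threshold of 0.05. The 503 effector calls may therefore hold more false ones than that threshold implies.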

Other observations

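The values here were looked at after the comparisons, and the genes below that the naming rule did not choose were picked after their values were seen. Immunoglobulin genes did not all differ alike between the genotypes. Ighm, the most abundant of those looked at, was 599.8 and 554.6 CPM in WT and KO naive libraries and 964 and 1143 CPM in effector libraries (edgeR adjusted p = 0.59 and 0.074). Igkc was 23.8 ± 7.30 CPM in WT effector and 58.9 ± 9.58 CPM in KO effector libraries (edgeR adjusted p = 0.13). Jchain, which joins secreted antibody chains, was 1.29 ± 1.35 and 5.39 ± 1.87 CPM in WT and KO naive libraries and 2.63 ± 0.808 and 6.93 ± 2.15 CPM in effector libraries. Ighg2b was 0.418 ± 0.322 and 4.96 ± 2.54 CPM in naive and 1.05 ± 1.46 and 9.16 ± 3.60 CPM in effector libraries. Of these and Ighg2c, only Ighg2c passed the test between genotypes, in both cell types, and it lost its call under 11 of 19 alternatives in each. The macrophage gene Lyz2 was 2.25 ± 2.81 and 8.93 ± 2.25 CPM in naive libraries, and Mpeg1 0.684 ± 0.649 and 3.31 ± 0.832 CPM, and neither passed.

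Every library held transcripts of both sexes, as it would if cells of male and female mice were pooled. Xist, expressed from the inactive X chromosome of females, ranged from 149.5 to 664 CPM, and the Y-linked Ddx3y from 40.1 to 96.4 CPM over the 12 libraries. Over libraries 1 to 3 and 4 to 6, and over 7 to 9 and 10 to 12, the libraries ranked in the same order for Xist, and so they did for Ddx3y, as they would if the naive and effector cells of a place came from the same mice. Neither gene passed the test between genotypes: the log2 fold change of Xist was -0.45 in naive and -0.12 in effector cells, and that of Ddx3y 0.23 and 0.30. Among genes of the sorted helper cells, Vipr1, a receptor for vasoactive intestinal peptide, was 311 and 299.6 CPM in naive but 48.7 and 31.5 CPM in WT and KO effector cells (difference -0.57, edgeR adjusted p = 0.0016). Sema4a, an immune semaphorin, was 199.7 and 214 CPM in naive and 173.7 and 120.9 CPM in effector cells (difference -0.62, edgeR adjusted p = 0.019).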
